A study of Mus musculus with 4 samples.

How the data were processed

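The series holds 4 Affymetrix arrays of RNA from mouse bone marrow cells, 2 labelled WT and 2 labelled Alox15-/-, the second group being named for a deletion of Alox15, the gene of arachidonate 15-lipoxygenase. Per the labels, cells that lacked lineage markers and carried c-Kit and Sca-1 were sorted by flow cytometry from C57BL/6 mice aged 8 weeks, and the labels call them haematopoietic stem cells (HSCs). This gate holds stem cells together with multipotent progenitors. The labels name the replicates of each group as biological but state no animals or pools, so the p-values measure the spread between these samples, which may be partly technical. Groups were taken from the sample titles.

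The deposited table gives log2 values, and per the submitters' processing notes they were made with Affymetrix Expression Console 1.1 and RMA, which subtracts background, quantile-normalizes the arrays and summarises each probe set. The table holds 45101 probe sets, of which 64 are Affymetrix controls. Its sorted columns differ by at most 0.0325, and each array takes 1195 to 1228 distinct values, so the deposited values are coarse and small differences can fall to 0. The number of arrays limits the precision. Per the labels' protocols, targets were made with a whole-transcript sense labelling kit, whereas the probe set identifiers belong to an array design made for antisense targets. Which of these describes the hybridised material is not given in the sources used here, and probe set values are reported as deposited.

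Probe sets were named through the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had no gene in the annotation used. Gene identifiers of 34754 named probe sets matched the RefSeq gene table of assembly GRCm38.p6, 204 did not, and 0 symbols changed. The deposited table names no genome build, so that table served only for names, chromosomes and gene order, and 18033 genes were placed. Only probe sets with 1 symbol were tested, with 1 probe set per gene, the one with the highest mean over the 4 arrays, which left 18194 genes. Of these, 9012 had more than 1 probe set. No filter on dim genes was used.

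The comparison was the arrays labelled Alox15-/- minus WT. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera, with a preset inter-gene correlation of 0.01, over 25 lists with at least 5 measured genes, adjusted over the lists. Of 599 list genes written before the data were examined, 548 were measured. Each list's median was also ranked among 10000 random lists matched on mean level, and its genes were adjusted over the list alone. The 50 measured genes on each side of Alox15 were compared with all others by Fisher's exact test for the share in the top 1 percent by absolute moderated t. The Alox15 gene was left out of its own list and of its neighbourhood.

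Named genes followed a rule fixed before the data were examined: Alox15; the 12 largest higher and 12 largest lower genes past the threshold, with places left open filled by genes with unadjusted p under 0.01 and groups that did not overlap; up to 4 genes per list; sex-linked genes; and neighbours of Alox15 in the top 1 percent. Predicted genes were counted but not named among the largest. Genes outside this rule are stated where they appear.

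The code was tested on simulated data for the same 2 against 2 comparison of 18194 genes. It recovered 11 of 67 genes changed by 1 on the log2 scale (16.4%), 65 of 67 changed by 2 (97.0%) and 65 of 66 changed by 4 (98.5%), with 6 false calls. All of these genes were changed in the same simulation, which makes the adjusted threshold easier to pass than in data with few changed genes. In the data themselves Slc35d3, at -2.22, had limma adjusted p = 0.206 and Hspa1b, at 5.25, had 0.260. The simulated shares therefore do not give the power of the real comparison. The 1 list shifted by 0.4 was called, and 0 of the 24 lists that were not shifted were. The simulated genes were drawn independently, so the 0 says nothing about false calls from correlation between a list's genes. Alternatives covered normalization, filters on dim genes, variance moderation, array weights, the choice of probe sets, a replicate block, leaving out each array, the thresholds, the list test and the size of the neighbourhood. Settings chosen after seeing the data are named as such. Figures were drawn with matplotlib 3.10.9.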

Results

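Expression was measured on 4 arrays, 2 labelled WT and 2 labelled Alox15-/-, in sorted mouse bone marrow cells without lineage markers that carried c-Kit and Sca-1. The design asked how the expression profile of these stem and progenitor cells differs between the genotypes. Pearson's r across probe sets, which are not independent replicates, was 0.988 between the WT arrays, 0.990 between the arrays labelled Alox15-/- and 0.986 to 0.988 between groups. The Gapdh control probe sets, which compare the transcript's ends, differed by 2.38 ± 0.01 on the log2 scale in WT and 2.15 ± 0.02 in the arrays labelled Alox15-/- (SD, n = 2 each), a gap of -0.23 between groups. For Actb the gap was 0.01.

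Alox15, which encodes the lipoxygenase named in the genotype, was far higher in the arrays labelled Alox15-/-, against the label. Its only probe set read 4.63 and 4.35 in the WT arrays and 10.68 and 10.75 in the arrays labelled Alox15-/-. The difference as measured was 6.22 ± 0.15 (SE), with limma adjusted p = 0.00133. In WT the probe set exceeded 24.1% and 20.5% of all probe sets, and in the arrays labelled Alox15-/- it exceeded 94.6% and 94.9%. The highest of 27 bacterial control probe sets, which should carry no mouse signal, read 4.95 to 5.17 on the 4 arrays, so the WT level was not clearly above background. Set against the mean of that highest control on the WT arrays, 4.97, the arrays labelled Alox15-/- were at least 53.5-fold higher. Of the 114 genes under the naming rule, Prom1, Mmp8 and Rhag lay below the highest bacterial control on all 4 arrays, 6 did so in WT alone and 5 in the arrays labelled Alox15-/- alone, at all probe sets of the gene. The positions of the deleted part and of the probe set are not given in the sources used here, so this probe set may check nothing about the deletion. Every direction below is therefore that of the arrays as labelled. Leaving out any 1 array kept the difference between 6.08 and 6.36. The call was lost in such fits, which have too few degrees of freedom to show dependence on any 1 array. Without variance moderation adjusted p was 0.703 over all 4 arrays.

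Alox15 was also the only gene past the threshold: 1 of 18194 genes was higher and 0 were lower by limma. The next adjusted p was 0.206. At an unadjusted p under 0.05 limma placed 1413 genes, against 909.7 by chance, 764 higher and 649 lower. Groups did not overlap for 7004 genes (38.5%, against 33.3% by chance). Genes measured on the same arrays are not independent, so neither excess is a test of the grouping. A mean-dependent prior variance gave 22 genes, 9 higher and 13 lower, and the count was 0 without any 1 of the arrays.

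Apart from Alox15, 23 genes were named by size among those with an unadjusted limma p under 0.01, no overlap between the groups and no predicted name. The inducible heat shock genes Hspa1b and Hspa1a, near-identical paralogs whose signals may not be separable, had differences of 5.25 ± 0.47 and 3.91 ± 0.38 (SE, n = 2 each). Pik3r6, a regulatory subunit of PI3-kinase gamma, differed by 2.29 and the helicase gene Dhx40 by 2.06. Further positive differences were 1.77 for Ublcp1, 1.76 for F13a1, 1.74 for Trim16, 1.47 for Scd3, 1.44 for Prom1, 1.42 for Ctsg and 1.31 for Gdpd1. Prom1 was below the highest bacterial control on all arrays, and Hspa1a was in WT. Hspa1b at the probe set used read 4.08 in WT replicate 1, below that control, and 5.53 in WT replicate 2, above it. Its other probe sets read 2.53 to 3.42 in WT, below it. A second probe set of Trim16 gave -0.96, one of Gdpd1 gave 0.02 and 2 of Ublcp1 gave 0.05 and -0.15. On the negative side, the myosin chaperone gene Unc45b differed by -2.92 ± 0.41, Ndnf by -2.35 ± 0.30 and Slc35d3 by -2.22 ± 0.16. Pde1c differed by -1.94, Chl1 by -1.83, Mid1 by -1.81, Pctp by -1.75, Mpped2 by -1.69 and Ldhd by -1.69. Other probe sets gave smaller differences, -0.47 to -0.17 for Pde1c, -0.63 to -0.20 for Chl1, -0.88 and -0.14 for Mid1, -0.90 for Pctp, -0.27 for Ldhd, -0.79 for Ndnf, 0.25 for Scd3 and 3.39 for Hspa1b. Zfhx2os differed by -1.59 and Kctd15 by -1.46, both below the highest bacterial control in the arrays labelled Alox15-/-, and Kctd15 ran from -1.96 to -0.96 without 1 array. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by -1.51 at the probe set used. Its other probe sets gave 0.89, 0.26, 0.38 and -0.46. Of the 114 named genes, 62 had several probe sets, of which 20 had probe sets of opposite sign and 25 others had one with a difference over 1.5 times smaller. None of the 23 genes named by size passed the threshold, with adjusted p from 0.206 to 0.548, and their lack of overlap was a condition of the choice. With the mean-dependent prior variance 10 of the 23 passed, Hspa1b, Hspa1a and Unc45b among them. Pik3r6, Dhx40, Ublcp1, Trim16, Gdpd1, Unc45b and Pctp lie on chromosome 11, as does Alox15, and that chromosome is taken up below.

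**Figure D1:**
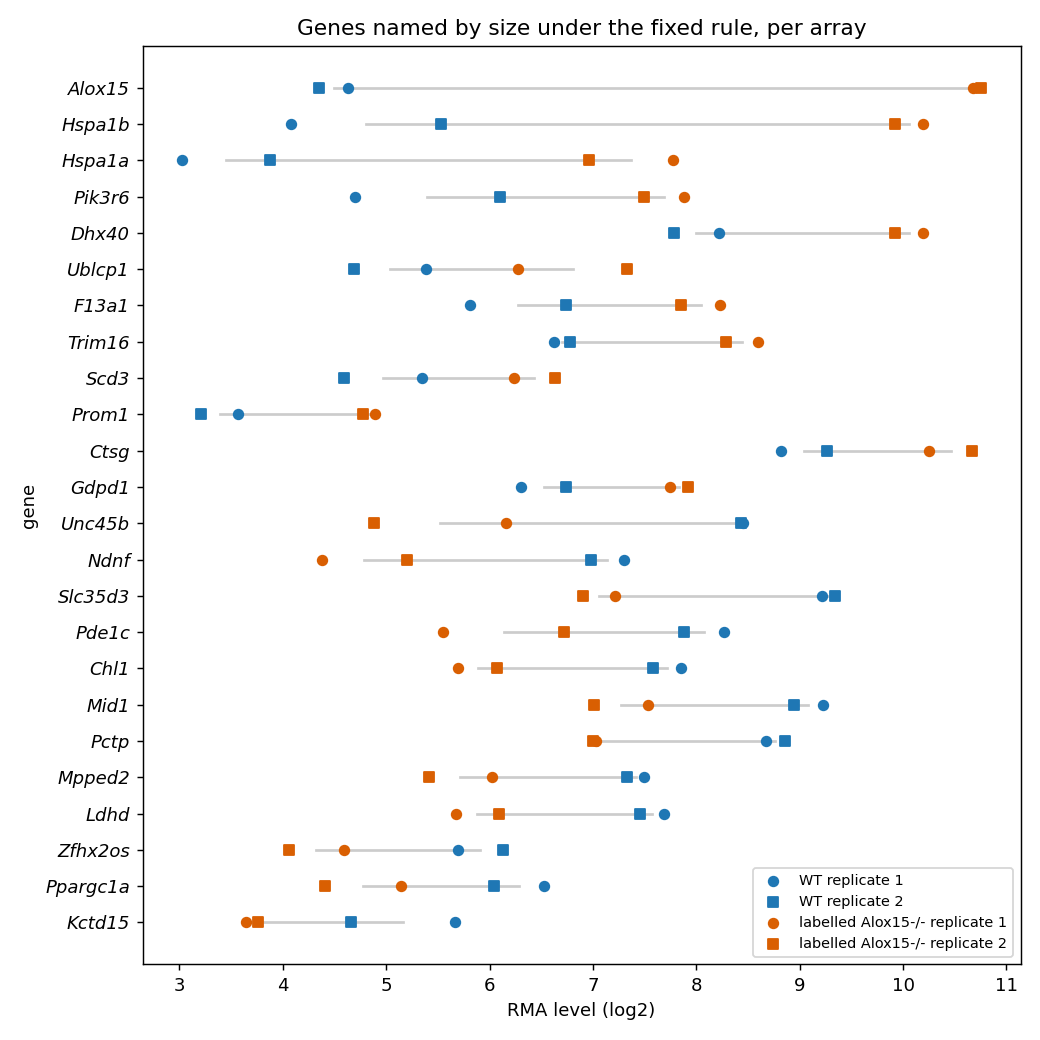
RMA levels (log2, horizontal axis) of Alox15 and the 23 other genes named by size (vertical axis), 1 point per array, with a grey line between the group means. Alox15 lies at 4.35 and 4.63 in WT and at 10.68 and 10.75 in the arrays labelled Alox15-/-, and of these genes only Alox15 passed the threshold with the default moderation; the other 23 were limited to an unadjusted p under 0.01, no overlap and no predicted name, so some larger differences are not drawn.

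Of 25 gene lists, 7 passed camera's threshold with the preset correlation. None did with an estimated correlation, which here rests on 2 arrays per group. That form of camera also uses only the residual degrees of freedom, here 2. Lists can hardly pass it with so few, so failing it says little against a list. With the estimate the 7 lists shared an adjusted p of 0.625, a tie made by the adjustment. Their unadjusted camera p included 0.0308 for granulocyte-monocyte genes, 0.0918 for S phase genes and 0.196 for mature neutrophil markers. For granulocyte-monocyte genes the estimated correlation was 0.0071, below the preset 0.01. The few degrees of freedom, not a larger correlation, thus ended that call. For each other called list the estimate was above 0.01. Among random lists matched on level, the medians of these 7 lists lay at percentile 0 for stem cell genes, 93.3 for macrophage and monocyte markers and 100 for the other 5. These percentiles take no account of correlation within a list, estimated at 0.279 for G2/M genes and 0.325 for mature neutrophil markers. They do not measure variation between arrays. Lists that camera did not call lay further out than the macrophage and monocyte markers: oxidative phosphorylation at 99.9, antioxidant and ferroptosis genes at 97.5, T and NK cell markers at 1.06, the PI3K-AKT pathway at 1.36 and erythroid and megakaryocyte genes at 5.37. The Gapdh gap of -0.23 separated the same groups of arrays. G2/M genes were higher in the arrays labelled Alox15-/-, with a median difference of 0.29, 26 of 27 higher and adjusted p = 4.11e-07 (adjusted p = 0.625 with an estimated correlation). Aurkb, a mitotic kinase, differed by 0.55, Cenpe by 0.51 and Anln by 0.50, whereas Mki67, the proliferation marker, differed by -0.63. S phase genes had a median of 0.20 with 23 of 25 higher and adjusted p = 0.000455 (adjusted p = 0.625 with an estimated correlation). Over 21 other settings that median ran from 0.11 to 0.20. Mcm2, of the replicative helicase, differed by 0.52, Rrm2 by 0.48, Ccne2 by 0.75 and Pola1 by 0.41, with -0.46 at a second Pola1 probe set. Without 1 array Ccne2 ran from 0.44 to 1.06. No gene of either list passed the threshold, over all genes or adjusted over the list alone.

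Granulocyte-monocyte genes had a median of 0.41, with 19 of 23 higher and adjusted p = 7.78e-07 (adjusted p = 0.625 with an estimated correlation). Adjusted over the list alone, 7 of them were higher and 0 lower, against 0 over all genes tested. They included the coagulation factor gene F13a1 (1.76), the granule protease gene Ctsg (1.42), Ms4a3 (1.02) and Anxa3 (0.88). Mature neutrophil markers, 0 of which are also in the granulocyte-monocyte list, were higher too and had a median of 0.70, with 12 of 13 higher and adjusted p = 0.000328 (adjusted p = 0.625 with an estimated correlation). S100a9 differed by 1.46, Ltf by 1.36, Mmp8, below the highest bacterial control on all arrays, by 0.59 and Itgam by -0.51, with 0 past the threshold adjusted over the list alone. Without 1 array S100a9 ran from 0.91 to 2.02, and Ltf was 0.72 without Alox15-/- replicate 1. S100a9 read 8.16 and 9.28 in WT and 10.38 and 9.98 in the arrays labelled Alox15-/-. Without WT replicate 1 the neutrophil median was 0.18 with adjusted p = 0.283, and without variance moderation adjusted p was 0.0654. The list's mean level relative to all arrays was -0.84 in WT replicate 1, 0.05 in WT replicate 2, and 0.53 and 0.26 in the arrays labelled Alox15-/-.

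Mast cell, basophil and eosinophil markers were higher, with a median of 0.49, 15 of 17 higher and adjusted p = 5.42e-05 (adjusted p = 0.625 with an estimated correlation). Prg2, an eosinophil granule protein gene, differed by 1.22, Cpa3 by 0.84, Siglecf by 0.72 and Hdc, which makes histamine, by 0.66. Prg2 lay below the highest bacterial control in WT and ran from 0.67 to 1.76 without 1 array, and Cpa3 ran from 0.54 to 1.13. Macrophage and monocyte markers, 2 of which are also granulocyte-monocyte genes, had a median of 0.12, with 15 of 18 higher and adjusted p = 0.040 (adjusted p = 0.625 with an estimated correlation). Adjusted over the list alone, 1 gene was higher, the chemokine receptor Ccr2 at 1.00 as measured (0.04 to 1.15 at its other probe sets), with a WT level below the highest bacterial control. That list's adjusted p was 0.636 without WT replicate 1 and 0.126 without Alox15-/- replicate 2, 0.279 and 0.792 without the lowest 30 and 50 percent of genes, and 0.212 without variance moderation.

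Stem cell genes were the only list of the 7 called that was lower, with a median of -0.26, 29 of 38 lower and adjusted p = 5.42e-05 (adjusted p = 0.625 with an estimated correlation). Over 21 other settings the median ran from -0.30 to -0.17. The list's mean level relative to all arrays was 0.11 in each WT array, -0.04 in Alox15-/- replicate 1 and -0.18 in Alox15-/- replicate 2. Adjusted over the list alone, 3 genes passed. Egr1, an immediate early transcription factor, differed by -1.34 and Hlf, a stem cell transcription factor, by -0.77, while Thy1, a surface marker, differed by 1.21.

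**Figure D2:**
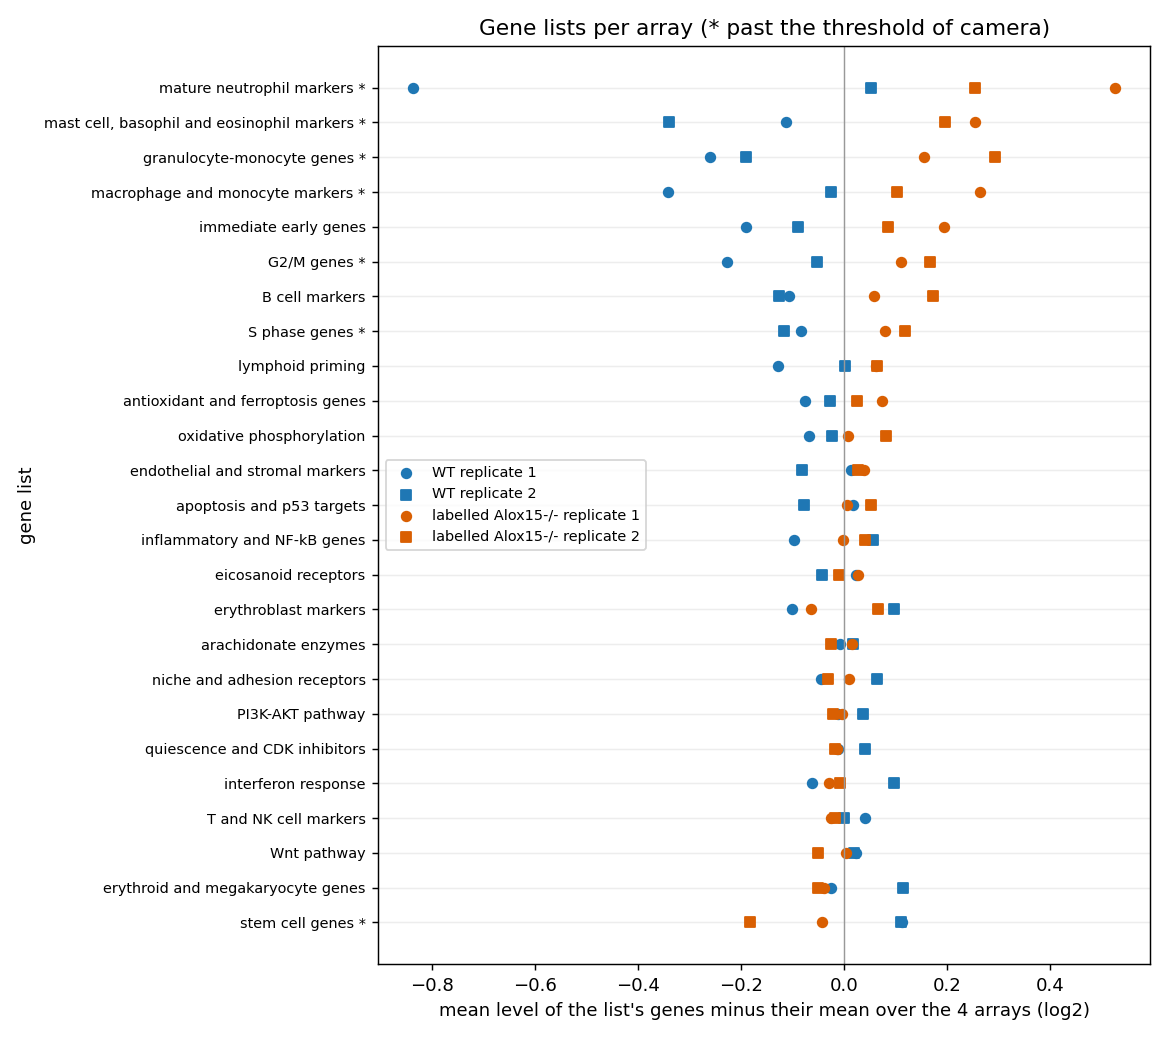
Mean log2 level of each list's genes relative to their mean over the 4 arrays (horizontal axis), 1 point per array and list (vertical axis), with asterisks for lists past camera's threshold. Mature neutrophil markers lie at -0.84 in WT replicate 1, apart from 0.05 in WT replicate 2.

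The other 18 lists did not pass camera's threshold. Arachidonate enzymes, the pathway of Alox15, had a median of 0.01 over 28 genes (adjusted p = 0.780), with Tbxas1 at -0.55, Ptges2 at -0.41, Ephx2 at -0.36 and Alox5ap at 0.31. Eicosanoid receptors had -0.03 (adjusted p = 0.783), with Fpr2, below the highest bacterial control in WT, at 1.02 and at 0.21 without Alox15-/- replicate 2, and Pparg at -0.54 and at -0.18 without WT replicate 2. Erythroid and megakaryocyte genes had -0.05 (adjusted p = 0.631), and 2 of them were higher when adjusted over the list alone, the erythroid factor Klf1 at 0.87 and Selp at 0.75. Immediate early genes had 0.01 (adjusted p = 0.905), and Hspa1b, Hspa1a and Egr1 passed when adjusted over the list alone. Lymphoid priming had 0.05 (adjusted p = 0.625), with Igll1 at 0.57 (0.06 at its other probe set), Rag1 at 0.52, Cd48 at 0.43 and Ebf1 at -0.42, which had probe sets of both signs. Quiescence and CDK inhibitors had 0.01 (adjusted p = 0.710), with Cdkn1a at 1.04 (0.33 at another probe set) and Ndn at -1.13. The PI3K-AKT pathway had -0.10 (adjusted p = 0.662), with Sgk1 at 0.84 and Inpp4b at -0.78. The Wnt pathway had -0.02 (adjusted p = 0.662), with Tcf7l1 at -0.88 and Dvl1 at -0.51 (-0.11 and -0.10 at other probe sets), and Dvl2 at 0.59 (-0.34 at its other). Apoptosis and p53 targets had -0.01 (adjusted p = 0.919) and inflammatory and NF-kB genes 0.02 (adjusted p = 0.792), with Tlr2 at -0.61 and Socs3 at 0.54. Interferon response genes had -0.06 (adjusted p = 0.294), with Irf9 at -0.49 and Cxcl10 at 0.68, and without WT replicate 1 they passed at -0.16 (adjusted p = 0.0348). Of these genes, Alox5ap ran from 0.20 to 0.42 without 1 array, Ptges2 from -0.58 to -0.23, Rag1 from 0.31 to 0.74, Ndn from -1.54 to -0.72, Sgk1 from 0.56 to 1.12, Tcf7l1 from -1.29 to -0.47, Dvl2 from 0.27 to 0.91, Socs3 from 0.16 to 0.92 and Cxcl10 from 0.18 to 1.19. Ebf1 ran from -0.56 to -0.27.

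Antioxidant and ferroptosis genes had a median of 0.09 (adjusted p = 0.393), with Gclm at 0.63, and oxidative phosphorylation genes 0.09 (adjusted p = 0.173), with Ndufv1 at 0.32. Both passed with a mean-dependent prior variance, at adjusted p = 0.0480 and 0.00171, and oxidative phosphorylation genes without moderation at 0.0264. Niche and adhesion receptors had -0.01 (adjusted p = 0.765), with Acvr1 at 0.51 and its other probe sets at -0.32 and -0.80, and Tgfbr2 at -0.38. Of other cell types, B cell markers had 0.11 (adjusted p = 0.201), with Jchain at 1.00 and Pou2af1, below the highest bacterial control in WT, at 0.73, and passed without Alox15-/- replicate 1 at 0.30 (adjusted p = 0.0141). T and NK cell markers had -0.12 (adjusted p = 0.905), with Nkg7 at 0.51 and Lat at -0.36. Erythroblast markers had 0.02 (adjusted p = 0.940) and endothelial and stromal markers 0.06 (adjusted p = 0.905), with Sparc at 1.32 (0.80 and -0.02 at its other probe sets) and Tek at -0.72. Without 1 array Gclm ran from 0.34 to 0.92, Jchain from 0.56 to 1.45 and Tek from -1.05 to -0.39. Median and mean had opposite signs for arachidonate enzymes, eicosanoid receptors, quiescence genes, and apoptosis and p53 targets. Camera's direction was opposite to the median for arachidonate enzymes, quiescence genes, apoptosis and p53 targets and immediate early genes.

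Of sex-linked genes, Eif2s3y on the Y chromosome differed by -0.38, Kdm5d by -0.31, Uty by 0.01 and Xist by 0.05, with -0.17 and -0.98 at the other Xist probe sets. On the 4 arrays Eif2s3y read 10.08 to 10.62 and Kdm5d, also on the Y chromosome, 9.85 to 10.29. Xist read 4.59 to 5.69, around the highest bacterial control. Transcripts of the Y chromosome were thus read on every array of both groups. Without 1 array Eif2s3y ran from -0.52 to -0.23 and Kdm5d from -0.43 to -0.18, while Uty and Xist changed sign. None passed the threshold. The 100 measured genes beside Alox15 on chromosome 11 held 2 in the top 1 percent by absolute moderated t (2%), 6330403K07Rik, below the highest bacterial control in the arrays labelled Alox15-/-, at -1.32 and Zzef1 at -0.74 (0.06 and 0.03 at its other probe sets), against 0.989% of other genes. The odds ratio was 2.04 (95% interval 0.242 to 7.68, two-sided Fisher's exact test, p = 0.262). The odds ratio was 3.11 without WT replicate 1 and 1.01 without any 1 of the other arrays. The neighbourhood passed in 6 of 21 other settings. These left out dim genes, counted several probe sets of a gene as separate units, or took 100 or 400 genes on each side. The 400 genes were chosen after seeing the data. In these 6 settings the odds ratio was 2.60 to 4.31 (Fisher's exact p from 3.86e-07 to 0.0499).

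**Figure D3:**
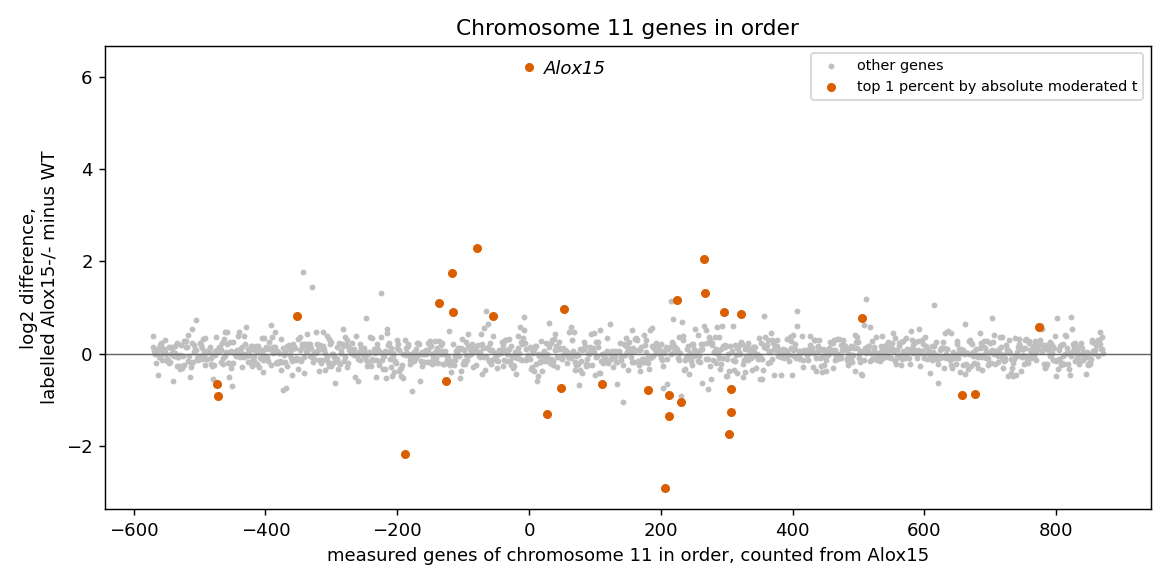
Log2 difference between the arrays labelled Alox15-/- and WT (vertical axis) for the measured genes of chromosome 11 in order, counted from Alox15 (horizontal axis), with genes of the top 1 percent by absolute moderated t in colour. The plot was drawn after seeing the data; besides Alox15 it shows 31 coloured genes, 14 higher and 17 lower, of which 2 lie within 50 genes of Alox15.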

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

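Leaving out all chromosome 11 genes and widening the neighbourhood to 400 genes were chosen after seeing the data; the other settings were not. Normalizing again, centring and cyclic loess gave 1 gene, Alox15, and 7 lists. A mean-dependent prior gave 22 genes, testing every named probe set 2 (with Fam107b), and leaving out chromosome 11 genes or any 1 array 0, the last with a lone array assumed to vary like the other group. Without moderation the 1 gene was Rac2 instead (it and Fam107b are named after their values were seen), whose arrays are equal within each group as deposited, and Alox15 stayed at 6.22 with adjusted p = 0.703 (2.49e-05 to 0.703 over 17 alternatives). Without 1 array Alox15 lay between 6.08 and 6.36. Lists numbered 4 of 19 tested without the dimmest 50 percent of genes, where 6 lists, mature neutrophil and mast cell markers among them, had under 5 genes left and were not tested, and macrophage and monocyte markers turned in camera's direction (median 0.0638), 0 with an estimated correlation and 0 with fry, and 6 to 8 without 1 array. The neighbourhood's odds ratio was 4.24 and 4.31 without the dimmest 30 and 50 percent (Fisher's exact p = 0.0177 and 0.0171), 3.07 and 3.06 over named and all probe sets (p = 0.0271 and 0.0274), 2.60 with 100 genes on each side (p = 0.0499), 3.56 with 400 (p = 3.86e-07) and 0 with 25. Over named and all probe sets, several probe sets of 1 gene counted as separate units. With 1 value per gene, the mean of its probe sets, the odds ratio was 3.11 (Fisher's exact p = 0.0779). It was 1.01 with the mean-dependent prior or no moderation, 1.00 for the top 5 percent, and 1.01 to 3.11 without 1 array. The cause was not tested. Replicates share only a number. Deviations correlated at -0.0214 for the same number, and with 2 arrays per group the 0.0214 for the other number is its mirror by construction. The replicate block left 1 gene, 7 lists and an odds ratio of 2.04. Of the 113 other named genes, 12 passed, each with the mean-dependent prior, and 9 that had not passed changed sign in some setting. The direction of the list test turned for uncalled lists in 40 instances. Among these were fry's directions for immediate early genes and for niche and adhesion receptors, the rest being camera's. Without some array, 44 of the 113 moved by over 1.5 times or changed sign. Alox15 in WT lay within the range of the bacterial controls, so its WT level was not clearly above background.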

Other observations

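All tests of explanations in this part were chosen after the results were seen, apart from the planned neighbourhood of 50 genes on each side. Heat shock genes were looked at after the values of Hspa1a and Hspa1b were seen. All 4 probe sets of Hspa1a and Hspa1b differed by 3.39 to 5.25. Dnajb1, their co-chaperone, differed by 0.07 and 0.52 at its 2 probe sets, Hspd1 by 0.07 and Hsph1 by -0.23 and -0.27. Of 4 Hspa8 probe sets, 1 differed by 1.08 and the other 3 by 0.00 to 0.02. Probe sets of Hsp90aa1 differed by 0.04 to 0.42, Hspe1 by 0.10 and 0.12, Bag3 by 0.45 and Hspa1l by 0.70. Hspa1l read 4.91 and 7.09 in WT and 6.59 and 6.81 in the arrays labelled Alox15-/-, so its groups overlapped. Hspb1 differed by 0.15 and -0.15, and Hspa5 by -0.02, 0.02 and 0.26. None of these passed the threshold with the default moderation.

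The Alox15 signal runs against its label. A single exchanged array is argued against by the gap of 6.04 between the nearest arrays of the 2 groups, while arrays within a group differ by at most 0.28. An exchange of both groups could give the same difference of 6.22 and stays open, since no independent mark of the targeted allele was measured. A transcript of the targeted allele outside the deleted part may also be read, but only 1 Alox15 probe set exists here and a second would be needed. These cannot be told apart, and a biological effect of the genotype on the gene was not tested separately.

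Chromosome 11, which carries Alox15, held 31 of its 1442 genes in the top 1 percent, an odds ratio of 2.43 (1.59 to 3.61, Fisher's exact adjusted p = 0.000814 over 20 chromosomes), and chromosome 6 came next at adjusted p = 0.0726. A stretch of another strain linked to the targeted gene is a candidate explanation, although the labels give both groups 1 strain. These 31 genes lay on average 268 genes from Alox15 against 379 for the others of the chromosome (two-sided permutation test, p = 0.00791), and 14 were higher and 17 lower, with Unc45b, Dhx40, Pctp and Hlf among them. The planned 100 nearest genes did not pass, with an odds ratio of 2.04 (6 of 21 other settings did), the densest run (11 within 50 genes of its centre) was centred 257 genes from Alox15, and neighbouring genes are not independent in the permutation. Sequence differences under the probes stay open. Among such genes with several probe sets, 3 of 16 on chromosome 11 (18.8%) and 25 of 80 elsewhere (31.3%) had a probe set of opposite sign (Fisher's exact p = 0.382). A higher share on chromosome 11 was the outcome written for this cause. The share was lower, but 16 genes are too few to decide.

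Cell cycle and granulocyte-monocyte lists were higher together in the arrays labelled Alox15-/-, beside markers of mature neutrophils and of mast cells, basophils and eosinophils (adjusted p = 0.625 for each with an estimated correlation) and a Gapdh gap of -0.23. Mature cells mixed into the sort, which depletes lineage-positive cells, divide little, so they would not raise the cell cycle genes. Of these, 26 of 27 G2/M and 23 of 25 S phase genes were higher, with a median of 0.25 over both lists. These values argue against mature cells as the source of the cell cycle part, although Mki67 was lower at -0.63. Whether that rise exceeds the variation between arrays stays undecided with that adjusted p. Mature cells stay open for the granulocyte-monocyte part. Against WT replicate 2 alone its median was 0.35, that of the neutrophil markers 0.18 and that of the mast cell, basophil and eosinophil markers 0.54. A larger share of committed progenitors in the gate, RNA quality, which the Gapdh gap leaves open, or the genotype itself may equally be the source and was not tested. The 3 splits of the 4 arrays are too few for a share under 0.05, 1 of them (the labelled one) calling as many as 7 lists, and the highest other 1, mature neutrophil markers, for WT replicate 1 and Alox15-/- replicate 2 against the others.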
